A study of Mus musculus with 16 samples.

How the data were processed

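Bulk RNA-seq had been made from epithelium and mesenchyme of parotid and submandibular glands of mouse embryos, with 4 libraries in each of 4 groups, taken from the sample titles. Per the labels' protocols the libraries were made with a full-length cDNA kit and a tagmentation kit, which do not mark the strand of a read, and the labels call the 4 samples of a group independent biological replicates. Per the submitters' processing notes the tools were STAR 2.5.2a and edgeR, and the build was GRCm38, also called mm10. The read counter and the gene annotation are not given in the sources used here. The deposited raw counts were whole numbers for 48709 gene features and 92 synthetic ERCC spike-in features. A further table of counts deposited by the authors held 23400 of these features, those with at least 6 counts in 1 or more libraries, with values equal to the raw table. Of these, 23380 were genes and the rest spike-in features. The third deposited table held a normalized signal, which the authors' table names as CPM: recomputing CPM with edgeR's TMM scaling gave it to within a relative difference of 4.98e-15. It had 23482 lines for these 23400 features, because some were repeated. Replicates were compared before averaging. In all 24 pairs of libraries within a group the counts differed by more than sampling noise, with a chi-square per gene of 10.5 to 54, so no library was a second deposit of another. This does not show that the samples were independent, which rests on the labels alone.

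The raw counts were tested and the signal table was used only for that comparison. Symbols came from the deposited table for 23380 genes and from a GENCODE table for 25049, and 280 genes had none. Spike-in features were left out of library sizes and tests. They held 0.00115 to 0.00651% of the counts of a library. Total gene counts are given with the description of the groups, and the 10 genes with most counts held 2.24 to 4.36% of a library. TMM factors were 1.075 to 1.087 in submandibular mesenchyme and 0.9256 to 1.007 in the other groups. The filter filterByExpr on the 4 groups kept 18191 genes, which held at least 99.88% of the gene counts of every library. Means and SDs are of CPM over the 4 libraries of a group. Principal components used log2 CPM with a pseudocount of 2 counts.

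One model with a coefficient for each group was fitted to all 16 libraries with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood, robust), and 5 contrasts were tested: parotid minus submandibular in epithelium and in mesenchyme, epithelium minus mesenchyme in each gland, and the difference of the gland contrasts between the layers. Genes with a Benjamini-Hochberg adjusted p under 0.05 are counted as called, and those that also changed by at least 2-fold are counted separately. The SE of a log2 fold change is its size divided by the square root of the F statistic. Fitted log2 fold changes include edgeR's prior count. For genes with 1 to 3 counts in all in a group, ratios of CPM are given with a 95% exact counting interval, and for a group with no count a lower bound that puts the group at 3 counts in all. These intervals and bounds cover counting error only.

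The groups, tests, 32 gene lists, the rule for the genes named and most alternatives were chosen before the data were examined. The rule took, among genes with a mean of at least 10 CPM in the higher group and libraries of the groups that did not overlap, the 8 called genes with the largest log2 fold changes in each direction of a gland comparison. It took 5 in each direction between the layers by the smaller of the changes in the glands, and for the interaction 4 in each direction among genes with at least 10 CPM in 1 group. From each list it took up to 4 called members with the largest changes, and members not called may be named. Some of the genes that this rule took are not reported here. The lists were marker genes of epithelium, mesenchyme, endothelium, neurons, Schwann cell lineage, macrophages and leukocytes, erythroid cells, skeletal muscle, cartilage, bone, stratified oral epithelium, and smooth muscle and pericytes; end bud progenitors, duct and basal progenitors and secretory products; FGF ligands, FGF response and receptors, WNT ligands and modulators, WNT response, the BMP and TGF-beta, hedgehog, retinoic acid, and EGF, neuregulin and EDA pathways; and craniofacial patterning transcription factors, HOX genes, basement membrane, neurotrophic factors and axon guidance, proliferation, immediate early and heat shock genes, hypoxia and glycolysis, mitochondrially encoded genes, and sex chromosome balance. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with adjustment over the lists of a contrast, and again with a correlation estimated from the data. Members were also counted adjusted over the list alone. Alternatives were other scalings, DESeq2 1.42.0, limma-voom, other filters, fry, glmTreat against 1.5-fold, fits to the 8 libraries compared, a block for the replicate number, and leaving out each library in turn. How many genes of a list reached 1 CPM was counted after seeing the data.

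Whether equal replicate numbers pair libraries was checked before the calls of the fits were compared, from the correlation of the deviations of same-numbered libraries from their group means over 10163 genes with a mean log2 CPM above 3. In the epithelia of the glands the correlations were 0.39, 0.15, 0.13 and 0.13, all above 0.1, and 6 of 8 libraries correlated best with the one of their own number, so the numbers were taken to pair them. This rests on the data alone, since no label says that a number marks a shared litter, day or animal. In submandibular epithelium the replicate numbers follow the sample names sorted as text, not by the numbers those names end in. The replicate numbers may therefore only be an order of listing, and the pairing is uncertain. After this outcome was known the check was also run over all 18191 tested genes, where the correlations were 0.16, 0.072, 0.027 and 0.02 and would not have met the limit. For a time that form was made the deciding one, and the first form was then restored.

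The procedure was tested on simulated data. Counts were drawn around 1 common mean per gene for all groups, with the dispersions and library sizes of the data. For each contrast 200 genes with a mean of at least 1 CPM were changed in 1 group, 50 at each fold. In the real comparisons 20.9 to 67% of genes were called, so the shares recovered and falsely called there may differ. In the epithelium contrast, on 17639 genes, 32% of genes changed 1.5-fold were recovered, 66% at 2-fold, 90% at 4-fold and 96% at 8-fold, and 1.39% of calls were false. In the mesenchyme contrast, on 17630 genes, the shares were 50, 68, 92 and 96% with 3.77% false calls, and for the interaction, on 17637 genes, 12, 48, 82 and 96% with 6.3%. Between the layers 72% were recovered at 2-fold in parotid (17628 genes, 6.88% false calls) and 64% in submandibular gland (17563 genes, 5.81%). The sample names carry index numbers that form separate blocks for the glands, so a batch that follows the gland cannot be told apart from it, and no value within a batch could be had.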

Results

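RNA was sequenced from 16 libraries of mouse salivary gland tissue taken at embryonic day 13, from wild-type animals of the outbred ICR strain. The libraries fell into 4 groups of 4, which the labels call independent biological replicates: parotid epithelium, parotid mesenchyme, submandibular epithelium and submandibular mesenchyme. The epithelium forms the branching gland and the mesenchyme is the connective tissue around it. The gene counts of a library summed to 21307466 to 23885698 in parotid epithelium and 19090077 to 27646844 in submandibular epithelium. In mesenchyme they summed to 19080629 to 25846015 in parotid and 16912258 to 18583164 in submandibular gland. The title of the series concerns recombination of salivary tissues. The comparisons made here ask how the separated layers of the 2 glands differed, and whether the gland difference was the same in both layers. The design text also speaks of cultured glands, while the sample titles and protocol speak of tissue harvested at that stage, so a period in culture before RNA isolation could not be ruled out from the labels.

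The first principal component of log2 CPM (counts scaled to a common library total) held 70.8% of the variance and parted epithelium from mesenchyme. The next held 10.7% and parted the glands in mesenchyme, where the 4 libraries of each gland lay close together, with a smaller step between the glands in epithelium. A further 5.64% lay along a component that parted the glands in epithelium.

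**Figure D1:**
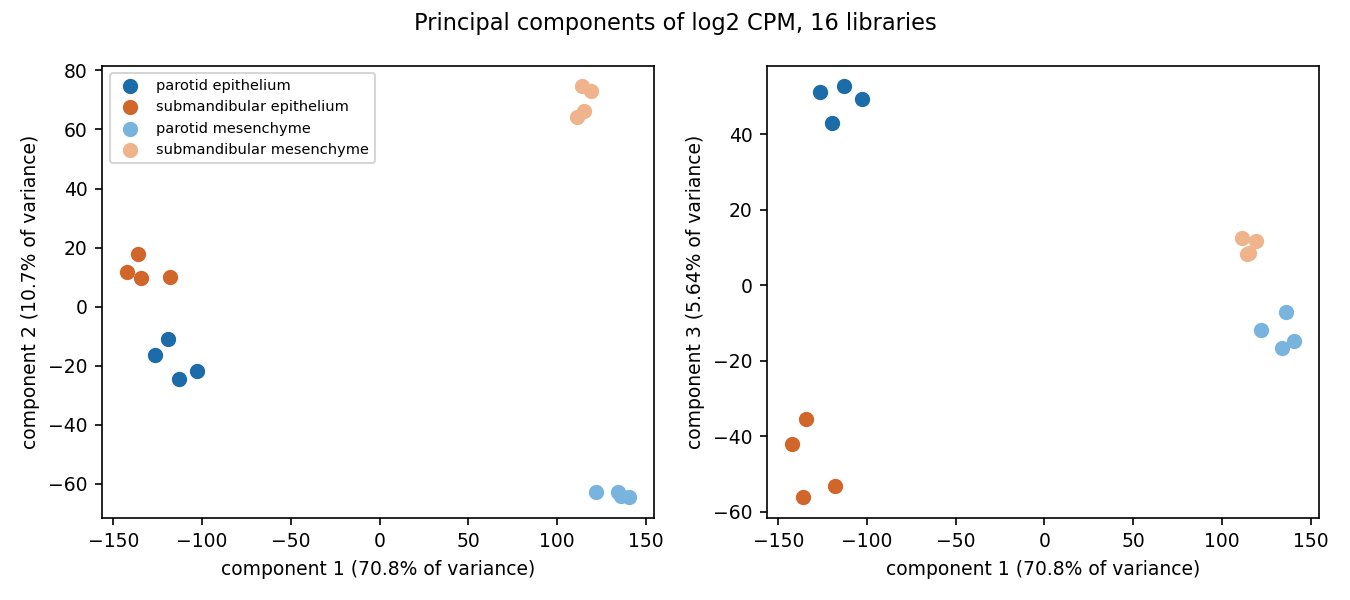
Scores of the 16 libraries on the first 3 principal components of log2 CPM, one point per library, coloured by group. The axes give each component's share of the variance (70.8, 10.7 and 5.64%). The 4 libraries of each group sit together and apart from the other groups.

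Epithelium and mesenchyme were compared within each gland, which also checks the separation of the layers that the labels name. Ehf, a transcription factor of glandular and other simple epithelia, was at 437 ± 103 CPM (SD, n = 4) in parotid epithelium against 0.693 ± 0.998 in parotid mesenchyme, and at 218 ± 60.3 against 0.29 ± 0.227 in the submandibular gland. The tight junction genes Cldn6 and Cldn8 reached 209 ± 10.4 and 78.6 ± 17.5 CPM in parotid epithelium and 188 ± 26.1 and 123 ± 12 CPM in submandibular epithelium, with means of at most 0.536 CPM in every mesenchyme group. The serine protease gene Tmprss2 had no count in parotid mesenchyme, so its 41.1 ± 13.8 CPM in parotid epithelium were at least 1140 times higher. Prom2, which encodes a protein of membrane protrusions, was higher in parotid epithelium by 1220 times (counting interval 219 to 48300).

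On the mesenchymal side stood Fgf10, the growth factor that drives branching of salivary epithelium, at 456 ± 127 CPM in parotid and 365 ± 26.3 CPM in submandibular mesenchyme, against 1.21 ± 1.06 and 0.347 ± 0.256 CPM in the epithelia. Prrx1, a homeobox gene of limb and craniofacial mesenchyme, stood at 409.7 ± 48.6 and 594 ± 54.1 CPM in the mesenchymes and at 1.3 ± 0.83 and 1.99 ± 2.9 CPM in the epithelia. Ccdc85a, a coiled-coil gene, fell from 188 ± 70.9 CPM in parotid mesenchyme to 0.511 ± 0.673 CPM in its epithelium (log2 fold change -8.52, SE 0.56). Corin, a membrane protease gene, had no count in parotid epithelium and was at least 302 times higher in parotid mesenchyme. The serotonin receptor gene Htr7 was higher in parotid mesenchyme by 303 times (counting interval 103 to 1470). edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 11804 of 18191 genes between the layers of the parotid gland (5712 higher and 6092 lower in epithelium; 2521 and 4066 of these by at least 2-fold). In the submandibular gland it called 12186 (6063 and 6123; 3053 and 3994). In both glands 9606 genes were called, 96.3% of them in the same direction.

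All 20 epithelial identity genes were higher in the epithelium of each gland, also adjusted over the list alone; camera gave adjusted p = 3.76e-13 in parotid and 7.19e-14 in submandibular gland, and adjusted p = 0.187 with an estimated correlation and 0.198 in turn. Of the 20 mesenchymal identity genes, 19 were lower in parotid and 20 in submandibular epithelium, the same numbers adjusted over the list alone (adjusted p = 2.22e-10 and 2.22e-11; adjusted p = 0.305 with an estimated correlation and 0.18). All 20 proliferation genes were higher in epithelium in both glands, the same adjusted over the list alone. That list had adjusted p = 2.06e-07 and 2.93e-07, and adjusted p = 0.334 with an estimated correlation and 0.414. In all, camera called 12 lists in parotid and 13 in submandibular gland, and with an estimated correlation 0 and 0 (4 and 6 at an unadjusted p under 0.05). For epithelial identity in parotid gland the estimated correlation was 0.43, far above the preset 0.01. The form with an estimated correlation left this list uncalled although all 20 genes were higher. A list left uncalled by it is therefore not shown to be unchanged. End bud progenitor genes counted 11 higher and 1 lower of 13 (also adjusted over the list alone) in parotid epithelium, and 10 higher and 1 lower of 13 (also adjusted over the list alone) in submandibular epithelium. For them adjusted p = 1.63e-06 and 7.18e-06 (4.54e-07 to 1.55e-05 with 1 library left out, and 1.24e-06 to 1.35e-05 with 1 library left out), and adjusted p = 0.122 with an estimated correlation and 0.0868. Genes of the BMP and TGF-beta pathway counted 6 higher and 18 lower of 30 (also adjusted over the list alone) in parotid epithelium, and 4 higher and 17 lower of 30 (also adjusted over the list alone) in submandibular epithelium. For them adjusted p = 0.033 and 0.0273 (0.00924 to 0.0487 with 1 library left out, and 0.0131 to 0.051 with 1 library left out), and adjusted p = 0.552 with an estimated correlation and 0.495. WNT response genes counted 7 higher and 4 lower of 13 (also adjusted over the list alone) in parotid epithelium (adjusted p = 0.0375, and adjusted p = 0.608 with an estimated correlation), a call lost without parotid epithelium replicate 3 or parotid mesenchyme replicate 2 (0.0267 to 0.0537 with 1 library left out). Summed over the list, mesenchymal identity markers in parotid epithelium came to 2.02% of their level in parotid mesenchyme, and in submandibular epithelium to 2.38% of their level in its mesenchyme. Macrophage markers stood at 24.2% and 10.5% in the same terms. Cartilage markers went both ways, with 5 higher and 2 lower of 10 in parotid epithelium and 5 and 4 in submandibular epithelium, also adjusted over the list alone. They summed to 1880 ± 403 CPM in parotid epithelium against 79.8 ± 21.3 CPM in its mesenchyme, and to 1110 ± 373 against 123 ± 28 CPM in the submandibular gland. Of 11 Schwann cell lineage genes, 3 of which stand on other lists, 3 were higher and 5 lower in parotid epithelium than in its mesenchyme, also adjusted over the list alone. Their sum was 621 ± 123 CPM in parotid epithelium against 74.6 ± 34.6 CPM in the mesenchyme, of which Sox10, a factor gene that salivary end buds also express and that was picked after its values were seen, made 322 ± 59 CPM.

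**Figure D2:**
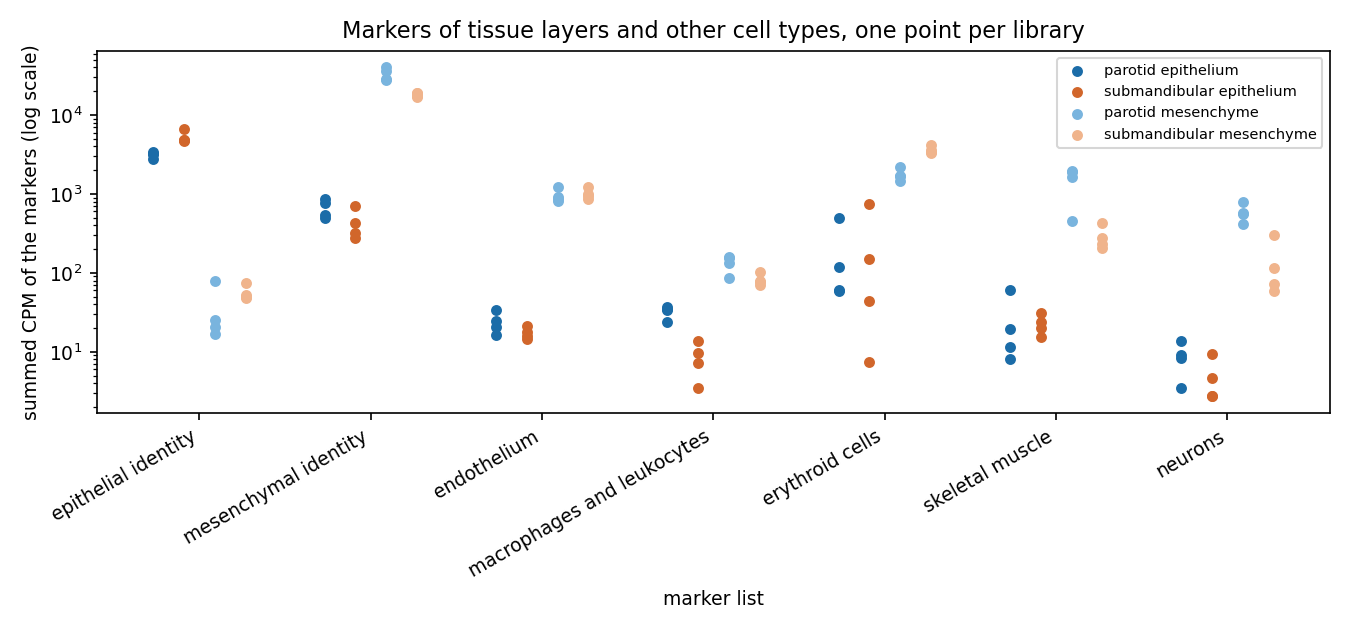
Summed CPM of 7 marker lists in each of the 16 libraries, one point per library on a log axis, coloured by group. Epithelial markers lie between 2800 and 6610 CPM in the epithelial libraries and between 17 and 79.4 CPM in the mesenchymal ones, and parotid mesenchyme replicate 4 lies below the other parotid mesenchyme libraries in skeletal muscle markers.

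Between the epithelia of the glands, genes of transcription factors went both ways. Gata2, a zinc finger factor, stood at 17.3 ± 6.55 CPM (SD, n = 4) in parotid and 0.221 ± 0.194 CPM in submandibular epithelium (log2 fold change 6.35, SE 0.51, adjusted p = 4.05e-07 by edgeR's quasi-likelihood test). The homeobox gene Tlx1, at 67.6 ± 4.63 CPM in submandibular epithelium, had 2 counts in all in parotid epithelium and was lower there by 2950 times (counting interval 816 to 24300). Foxa1, a forkhead factor that opens chromatin in many endoderm-derived organs, was at 0.378 ± 0.253 CPM in parotid against 116 ± 18.5 CPM in submandibular epithelium (log2 fold change -8.26, SE 0.41). Il33, a cytokine of the interleukin-1 family made by many epithelia, stood at 157 ± 60.6 CPM in parotid against 5.54 ± 1.1 CPM in submandibular epithelium, although parotid epithelium replicate 2 lay at 66.4 CPM and the other 3 at 184 to 190 CPM. Krt4, a keratin of stratified epithelia that do not cornify, reached 41.9 ± 5.28 CPM in submandibular epithelium and was lower in parotid epithelium by 1830 times (counting interval 506 to 15100).

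Further genes higher in parotid epithelium were Gphb5, a hormone subunit gene (42.2 ± 27 against 0.578 ± 0.239 CPM), Wfdc18, a secreted protein gene of the whey acidic protein family (32.8 ± 13.3 against 1.09 ± 1.11 CPM), and the phospholipase gene Plcb1 (50.6 ± 3.92 against 2.71 ± 0.369 CPM). The dynein chain gene Dync1i1 (12.4 ± 2.52 against 0.769 ± 0.518 CPM) and the T-box gene Tbx2 (35 ± 8.64 against 2.41 ± 2.18 CPM) were higher as well. Lower in parotid epithelium were the relaxin receptor gene Rxfp1, by 1600 times (counting interval 547 to 7760), and Scel, a precursor gene of the cornified envelope, at 0.0859 ± 0.142 against 10.3 ± 4.55 CPM. The forkhead gene Foxe1, known from the thyroid and pharynx, was at 0.483 ± 0.548 against 91.8 ± 38 CPM. Nkx2-3, with 4 counts in all in parotid epithelium, was at 13.6 ± 7.42 CPM in submandibular epithelium, and the pharyngeal T-box gene Tbx1 was at 0.118 ± 0.115 against 14.4 ± 8.15 CPM. In all, 3801 genes were called, 2033 higher and 1768 lower in parotid epithelium, of which 704 and 848 by at least 2-fold. Without submandibular epithelium replicate 1 the count was 2452. Leaving out that library together with parotid epithelium replicate 4, the epithelial libraries with the most erythroid counts and a choice made after seeing the data, gave 1846, of which 1790 were among the 3801. With the genes left out whose mean was higher in the mesenchyme than in the epithelium of either gland, 1399 of 7550 genes were called.

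**Figure D3:**
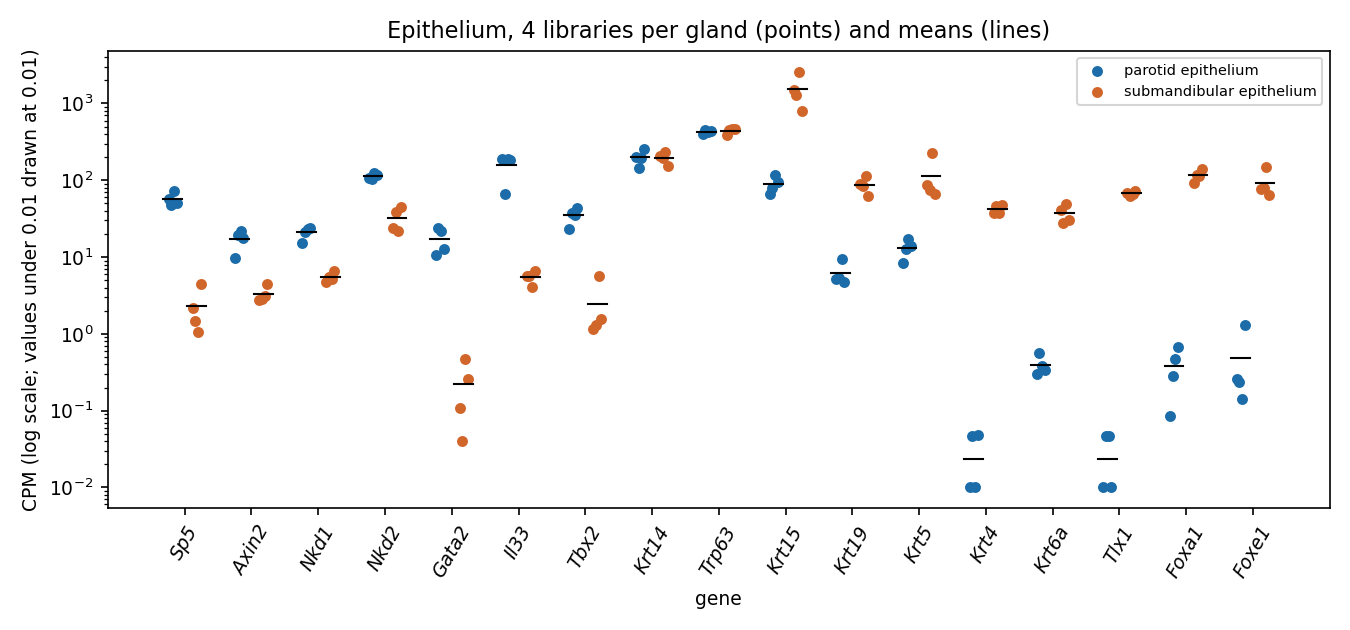
CPM of 17 genes in the 4 parotid (blue) and 4 submandibular (orange) epithelial libraries on a log axis, one point per library with a line at each group's mean; values under 0.01 are drawn at 0.01. Genes of the WNT response lie higher in parotid epithelium, Krt15, Krt19, Krt5, Krt4 and Krt6a lie higher in submandibular epithelium, and Krt14 and Trp63 overlap.

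Genes that respond to WNT signalling rose together in parotid epithelium, where 9 of 13 tested were higher and the other 4 not called, the same adjusted over the list alone. Sp5, a transcription factor gene and WNT target, was at 56.8 ± 10.8 against 2.3 ± 1.5 CPM (log2 fold change 4.60, SE 0.48). Axin2, a feedback inhibitor of the pathway, was at 17.1 ± 5.2 against 3.27 ± 0.772 CPM. The inhibitors Nkd1 and Nkd2 stood at 20.9 ± 4.01 against 5.5 ± 0.814 and 113 ± 10.3 against 32.2 ± 11.1 CPM. The list had camera adjusted p = 6.31e-08 (8.97e-09 to 6.38e-07 with 1 library left out), and adjusted p = 0.272 with an estimated correlation. Of the 13 tested duct and basal progenitor genes 7 fell and 1 rose, also adjusted over the list alone. Krt15 was at 89.5 ± 22 against 1553 ± 764 CPM, Krt19 at 6.13 ± 2.21 against 87.1 ± 20.6 CPM and Krt5 at 13 ± 3.56 against 113 ± 74.2 CPM, all keratins of duct or basal cells. The chloride channel gene Cftr stood at 1.88 ± 0.95 against 25 ± 9.17 CPM. Krt14 (200.2 ± 45.3 against 197 ± 32.6 CPM) and the basal cell factor Trp63 (431 ± 23.9 against 439.7 ± 36.9 CPM) were not called. Camera gave adjusted p = 0.000234 (0.00015 to 0.000681 with 1 library left out), and adjusted p = 0.289 with an estimated correlation. Genes of stratified oral epithelium fell in 8 of 12 tested (9 adjusted over the list alone), among them Krt6a at 0.394 ± 0.118 against 37.1 ± 10.1 CPM. This list had adjusted p = 2.15e-13 (3.66e-14 to 7.92e-11 with 1 library left out) and was also called by the other form of the test, at adjusted p = 0.00426 with an estimated correlation.

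The 20 epithelial identity genes, 6 of which also stand on other lists, included 7 that fell in parotid epithelium (8 adjusted over the list alone; adjusted p = 0.000609, and adjusted p = 0.603 with an estimated correlation; 0.00033 to 0.00657 with 1 library left out). Their sum was 3180 ± 271 CPM in parotid and 5230 ± 926 CPM in submandibular epithelium. Markers of other cells rose beside this. Of 12 macrophage and leukocyte genes 10 rose (11 adjusted over the list alone). C1qc and C1qa, genes of the complement system, stood at 4.06 ± 1.07 against 0.57 ± 0.507 CPM and at 1.95 ± 0.492 against 0.317 ± 0.296 CPM. This list had adjusted p = 4.54e-09 (5.97e-13 to 3.52e-07 with 1 library left out), and adjusted p = 0.272 with an estimated correlation. The list summed to 32.3 ± 5.63 CPM in parotid and 8.58 ± 4.38 CPM in submandibular epithelium, where 11 and 2 of the genes reached 1 CPM. Of 20 mesenchymal identity genes 9 rose, also adjusted over the list alone. The number was 4 without submandibular epithelium replicate 1, 5 without parotid epithelium replicate 3 or submandibular epithelium replicate 2 and 14 without submandibular epithelium replicate 3 (range 4 to 14 with 1 library left out). The twist factor gene Twist2 stood at 3.65 ± 0.616 against 0.57 ± 0.126 CPM and the collagen gene Col1a2 at 76.5 ± 29.1 against 15.3 ± 13.2 CPM. The test of the list gave adjusted p = 8.18e-05 (1.73e-10 to 0.000785 with 1 library left out), and adjusted p = 0.506 with an estimated correlation. Their sum was 670 ± 172 against 429 ± 187 CPM. In the mesenchymes the same markers summed to 33200 ± 6050 CPM in parotid and 18000 ± 1070 CPM in submandibular gland. Relative to the mesenchyme of the same gland, the sum in epithelium was 2.02% in parotid and 2.38% in submandibular gland. The higher sum in parotid epithelium therefore does not show a larger share of mesenchymal cells. Of 17 endothelial genes 8 rose and 1 fell (11 and 1 adjusted over the list alone), including the receptor gene Kdr at 0.807 ± 0.779 against 0.0724 ± 0.0884 CPM. The number that rose was 4 without parotid epithelium replicate 4 or submandibular epithelium replicate 1 and 5 without parotid epithelium replicate 2 (range 4 to 12 with 1 library left out). Most of these genes had few counts, and 6 reached 1 CPM in parotid and 4 in submandibular epithelium. The list summed to 23.9 ± 7.44 against 17.3 ± 2.97 CPM, and the libraries of the glands overlapped (16.4 to 33.8 against 14.4 to 21.2). The endothelial list had adjusted p = 0.000568, which became 0.0678 without the pair of libraries with the most erythroid counts, and adjusted p = 0.506 with an estimated correlation (8.43e-06 to 0.04 with 1 library left out).

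Of 16 genes of hypoxia and glycolysis 9 rose and 1 fell in parotid epithelium (10 and 1 adjusted over the list alone). The phosphofructokinase gene Pfkl was at 859.6 ± 153 against 436 ± 97 CPM and Bnip3, a mitophagy receptor gene induced by low oxygen, at 82.5 ± 24 against 45.4 ± 11.2 CPM. Camera gave adjusted p = 0.000122 (1.81e-06 to 0.00106 with 1 library left out), and adjusted p = 0.289 with an estimated correlation. Of 10 genes encoded in mitochondrial DNA 9 fell, also adjusted over the list alone. The respiratory chain genes mt-Co1 and mt-Nd4 stood at 626 ± 132 against 1234 ± 339.6 and 209 ± 27.4 against 401 ± 91.2 CPM. This list had adjusted p = 6.91e-07 (2.72e-09 to 3.72e-06 with 1 library left out), and adjusted p = 0.289 with an estimated correlation. Immediate early and heat shock genes, which respond within minutes to stress such as dissection, fell in 5 of 14 (7 adjusted over the list alone). Leaving out 1 library, this became 2 without parotid epithelium replicate 1 or 2 or submandibular epithelium replicate 1 or 4 and 3 without parotid epithelium replicate 3 (range 2 to 7). Fos stood at 144 ± 92 against 400.4 ± 173 CPM and Fosb at 3.54 ± 3.05 against 14.5 ± 12 CPM. That list had adjusted p = 0.012, lost without parotid epithelium replicate 2 (0.0522) or submandibular epithelium replicate 4 (0.134) within a range of 0.000579 to 0.134, and adjusted p = 0.603 with an estimated correlation. Of 24 genes of secretory products, 4 passed the expression filter. Agr2, a mucin-folding gene, was lower in parotid epithelium (0.481 ± 0.161 against 10.3 ± 1.54 CPM), also adjusted over the list alone. The secretory list had adjusted p = 0.0238, lost without parotid epithelium replicate 1 (0.0711) or submandibular epithelium replicate 4 (0.0613) within a range of 0.0126 to 0.0711, and adjusted p = 0.272 with an estimated correlation.

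The other lists were not called by camera in epithelium, where their adjusted p ran from 0.147 to 0.929. Exceptions with 1 library left out were HOX genes without parotid epithelium replicate 2 (0.0244) or submandibular epithelium replicate 2 (0.00259), within a range of 0.00259 to 0.15, and skeletal muscle without parotid epithelium replicate 2 (0.01), within a range of 0.01 to 0.902. Of 50 craniofacial patterning factors 9 were higher and 8 lower in parotid epithelium (10 and 8 adjusted over the list alone), with Isl1 and Barx1, homeobox genes of the oral and pharyngeal region, at 0.356 ± 0.237 against 23.1 ± 10.9 and 0.521 ± 0.45 against 27.4 ± 10.8 CPM. Of 30 genes of the BMP and TGF-beta pathway 6 rose and 4 fell (7 and 4 adjusted over the list alone). Id1, a target of BMP signalling, was at 4.12 ± 1.24 against 70.7 ± 24.2 CPM. The ligand gene Bmp4 stood at 0.295 ± 0.389 against 3.25 ± 1.09 CPM and Bmp2 at 3.84 ± 0.504 against 0.454 ± 0.313 CPM. Among 25 WNT ligands and modulators 5 rose and 4 fell (9 and 4 adjusted over the list alone), where the number that rose was 3 without parotid epithelium replicate 3 or 4 or submandibular epithelium replicate 1 (range 3 to 6 with 1 library left out). The ligand gene Wnt7b stood at 2.74 ± 0.98 against 59.5 ± 37.8 CPM. Of 16 genes of the retinoic acid pathway 5 rose and 3 fell (6 and 4 adjusted over the list alone), and the retinol dehydrogenase gene Rdh10 was at 107 ± 23.4 against 16.7 ± 5.03 CPM. FGF response genes and receptors counted 4 higher and 1 lower of 21 (4 and 3 adjusted over the list alone). Of these the number higher was 1 without parotid epithelium replicate 2 and 2 without submandibular epithelium replicate 1, 2 or 3 (range 1 to 5 with 1 library left out). The receptor gene Fgfr3 stood at 1.2 ± 0.22 against 18.3 ± 5.4 CPM. FGF ligands counted 1 higher and 2 lower of 12 (2 and 3 adjusted over the list alone), with Fgf9 at 30.1 ± 4.06 against 67.8 ± 7.36 CPM. With 1 library left out 0 to 2 FGF ligands were higher and 2 to 3 lower. Basement membrane genes counted 6 higher and 7 lower of 26 (7 and 7 adjusted over the list alone). The laminin gene Lama3 stood at 2.23 ± 0.186 against 23.1 ± 8.65 CPM and the collagen gene Col4a6 at 213 ± 31.2 against 58.5 ± 21.3 CPM. Of 13 end bud progenitor genes 3 rose and 3 fell (4 and 4 adjusted over the list alone). With 1 library left out 0 to 3 of them rose and 2 to 3 fell. Of 13 hedgehog genes 3 rose and 1 fell, also adjusted over the list alone.

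Between the mesenchymes of the glands the differences were more numerous. Vstm2a, a gene for a secreted immunoglobulin-domain protein, stood at 282 ± 96.8 CPM (SD, n = 4) in parotid and 0.681 ± 0.379 CPM in submandibular mesenchyme (log2 fold change 8.68, SE 0.41, adjusted p = 8.65e-10 by edgeR's quasi-likelihood test). The chemokine gene Cxcl14 was at 144 ± 40.3 against 0.464 ± 0.432 CPM, and the POU factor gene Pou3f3 at 48.6 ± 11.7 against 0.155 ± 0.0712 CPM. Nr5a2, a nuclear receptor gene, went the other way, at 1.03 ± 0.311 against 118 ± 5.8 CPM (log2 fold change -6.81, SE 0.33), as did the prolactin receptor gene Prlr at 0.463 ± 0.464 against 56.8 ± 14.7 CPM.

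Pantr1, a noncoding RNA gene beside Pou3f3, was higher in parotid mesenchyme by 1370 times (counting interval 379 to 11300). The histamine receptor gene Hrh1 was higher by 1340 times (counting interval 370 to 11000) and Areg, which encodes the EGF receptor ligand amphiregulin, by 571 times (counting interval 158 to 4720), each with 2 counts in all in submandibular mesenchyme. The glycosyltransferase gene Mgat4c was at 32.2 ± 16.2 against 0.172 ± 0.182 CPM and the cadherin gene Cdh8 at 111 ± 33.9 against 0.621 ± 0.141 CPM. In submandibular mesenchyme Acan, which encodes the proteoglycan aggrecan, was at 19.2 ± 6.57 CPM and lower in parotid mesenchyme by 533 times (counting interval 182 to 2590). Negr1, a neuronal adhesion gene, was at 1.39 ± 1.18 against 84.8 ± 5.8 CPM and the olfactomedin gene Olfm3 at 0.26 ± 0.305 against 22.9 ± 11.9 CPM. The acyltransferase gene Gpat3 was at 0.0703 ± 0.081 against 14.7 ± 6.3 CPM and the membrane protein gene Tmc3 at 0.256 ± 0.108 against 18.5 ± 4.59 CPM, and both are uncertain, since 30% and 43.9% of their exon bases overlap other genes and the libraries do not mark strand. In all, 6282 genes were called, 3785 higher and 2497 lower in parotid mesenchyme, of which 1622 and 1178 by at least 2-fold. In a fit to the 8 mesenchymal libraries alone, 6707 of 16420 genes were called, 3426 higher and 3281 lower, so that 51.1% of calls were higher in place of 60.3%. With the genes left out whose mean was higher in the epithelium than in the mesenchyme of either gland, 2898 of 7507 genes were called. Without parotid mesenchyme replicate 4 and submandibular mesenchyme replicate 3, which stood apart in muscle or neuron markers and were doubted after seeing the data, 5271 genes were called.

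**Figure D4:**
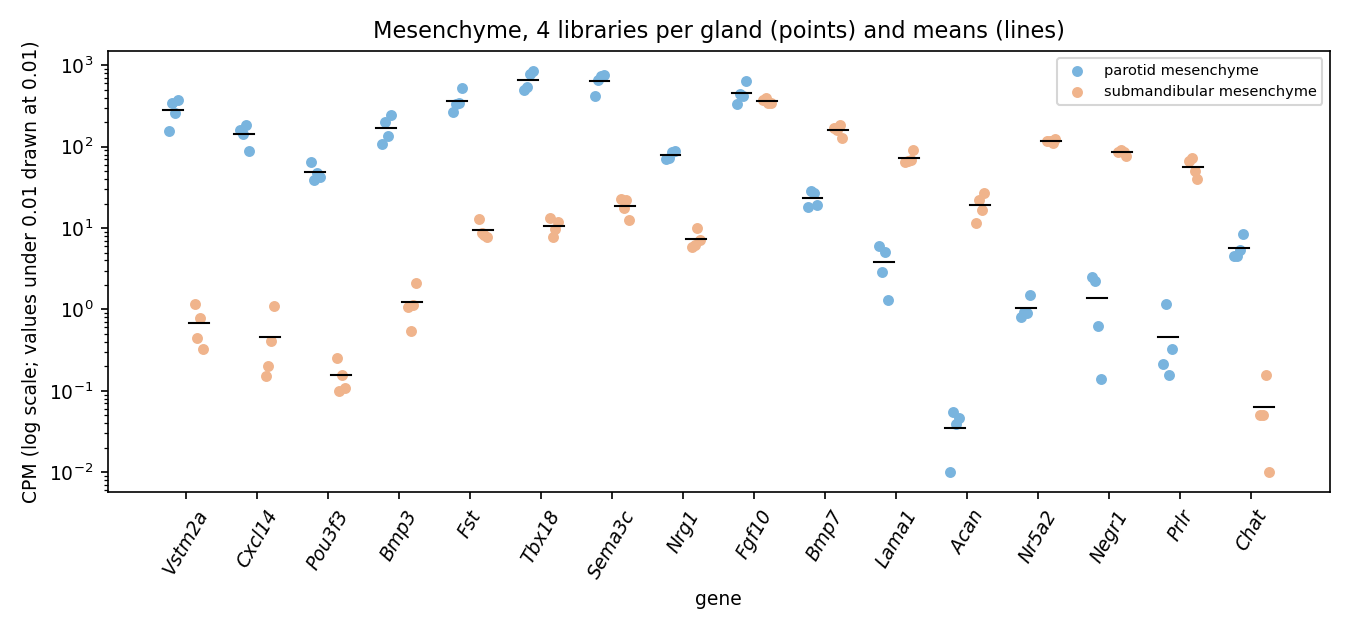
CPM of 16 genes in the 4 parotid (blue) and 4 submandibular (orange) mesenchymal libraries on a log axis, one point per library with a line at each group's mean; values under 0.01 are drawn at 0.01. The libraries of the glands overlap for Fgf10 and lie apart for each other gene drawn.

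Skeletal muscle genes rose in parotid mesenchyme in 15 of 16 tested (16 adjusted over the list alone). Myh3, the embryonic myosin heavy chain gene, was at 154 ± 83.9 against 19.8 ± 8.29 CPM and the actin gene Acta1 at 70.7 ± 39.8 against 7.89 ± 3.58 CPM. Parotid mesenchyme replicate 4 stood apart, with the list summing to 455 CPM against 1635 to 1929 CPM in the other 3. Camera gave adjusted p = 0.0245 for this list (3.69e-05 to 0.0439 with 1 library left out), and adjusted p = 0.854 with an estimated correlation. Of 16 genes of hypoxia and glycolysis 8 rose, also adjusted over the list alone. Ldha, the lactate dehydrogenase gene, stood at 901 ± 109.7 against 292 ± 47.4 CPM and the enolase gene Eno1 at 659.9 ± 76.6 against 269.7 ± 44.7 CPM. The test of the list gave adjusted p = 0.0245 (0.0166 to 0.0439 with 1 library left out), and adjusted p = 0.854 with an estimated correlation. The remaining lists were not called by camera in mesenchyme, with adjusted p from 0.0609 to 0.874, although many of their members were. Some of these lists were called when 1 library was left out. Camera then called 4 lists without parotid mesenchyme replicate 1, parotid mesenchyme replicate 3 or submandibular mesenchyme replicate 4, 5 without submandibular mesenchyme replicate 2 and 6 without parotid mesenchyme replicate 4, in place of 2. Over the 8 fits that each left out 1 library the adjusted p ran from 0.0166 to 0.1 for WNT response, 0.0179 to 0.135 for WNT ligands and modulators and 0.0358 to 0.142 for FGF ligands. It ran from 0.0391 to 0.152 for cartilage, 0.0395 to 0.153 for smooth muscle and pericytes, 0.041 to 0.2 for mitochondrially encoded genes and 0.0439 to 0.973 for epithelial identity.

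Of 16 neuron genes 7 were higher and 6 lower in parotid mesenchyme (7 and 8 adjusted over the list alone). The number lower was 10 without parotid mesenchyme replicate 2 (range 4 to 10 with 1 library left out). Prph, an intermediate filament gene of peripheral neurons, stood at 15.1 ± 6.57 against 0.168 ± 0.268 CPM and the acetylcholine-synthesis gene Chat at 5.75 ± 1.9 against 0.064 ± 0.0651 CPM, while Th, the tyrosine hydroxylase gene, was lower by 99.5 times (counting interval 17.4 to 3970). The list summed to 585 ± 160 CPM in parotid and 137 ± 113 CPM in submandibular mesenchyme, where replicate 3 held 303 CPM. Of 18 genes of the EGF, neuregulin and EDA pathways 9 rose and 5 fell (10 and 5 adjusted over the list alone). Nrg1 and Btc, genes of ligands, stood at 79.5 ± 9.43 against 7.3 ± 1.95 CPM and at 4.75 ± 0.97 against 0.092 ± 0.0801 CPM. The receptor gene Eda2r stood at 0.602 ± 0.383 against 10.9 ± 2.02 CPM. Among 30 genes of the BMP and TGF-beta pathway 9 rose and 6 fell (11 and 6 adjusted over the list alone). Bmp3 stood at 172 ± 62 against 1.22 ± 0.657 CPM, the activin antagonist gene Fst at 368 ± 109 against 9.39 ± 2.45 CPM and Bmp7 at 23.3 ± 5.3 against 162 ± 23.2 CPM. Of 25 WNT ligands and modulators 12 rose and 3 fell (12 and 4 adjusted over the list alone). The WNT agonist gene Rspo2 stood at 52.5 ± 19.2 against 4.53 ± 0.777 CPM and the antagonist gene Dkk2 at 312 ± 47 against 38.3 ± 14.8 CPM. WNT response genes rose in 6 of 13 (7 adjusted over the list alone).

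Of 50 craniofacial patterning factors 19 rose and 13 fell in parotid mesenchyme (20 and 15 adjusted over the list alone). The T-box genes Tbx18 and Tbx15 stood at 666 ± 174 against 10.6 ± 2.3 CPM and at 96.6 ± 16.8 against 0.906 ± 0.677 CPM. Axon guidance and neurotrophic genes counted 7 higher and 2 lower of 20, also adjusted over the list alone, with Sema3c, a secreted semaphorin gene, at 643 ± 160.1 against 18.8 ± 4.64 CPM. Of 16 retinoic acid genes 3 rose and 6 fell (3 and 7 adjusted over the list alone), with the binding protein gene Crabp1 at 170.5 ± 45.2 against 20.3 ± 7.44 CPM and Rdh10 at 75.4 ± 5.95 against 197 ± 35.5 CPM. Of 10 smooth muscle and pericyte genes 7 rose (8 adjusted over the list alone), with Acta2 at 209 ± 93.3 against 40 ± 7.73 CPM. FGF ligands counted 7 higher and 2 lower of 12 (7 and 3 adjusted over the list alone) and FGF response genes 12 and 3 of 21, also adjusted over the list alone. Of 10 cartilage genes 1 rose and 5 fell and of 7 bone genes 2 rose and 2 fell (1 and 5, then 3 and 2, adjusted over the list alone). Of 13 end bud progenitor genes 3 rose and 4 fell (3 and 5 adjusted over the list alone). The number that rose was 5 without submandibular mesenchyme replicate 1 (range 3 to 5 with 1 library left out), and the number that fell 2 without parotid mesenchyme replicate 2 or 3 (range 2 to 4 with 1 library left out). Of this list Sox9, a transcription factor gene of end buds and of cartilage, stood at 155 ± 34.8 against 9.45 ± 1.45 CPM. Basement membrane genes counted 10 higher and 6 lower of 26 (11 and 6 adjusted over the list alone), with the laminin gene Lama1 at 3.79 ± 2.12 against 72.7 ± 12 CPM. Mesenchymal identity genes counted 7 higher and 1 lower of 20, also adjusted over the list alone, with Postn, a matrix protein gene, at 3699 ± 1454 against 288 ± 10.6 CPM.

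Some lists had few or no calls. Of 17 endothelial genes edgeR called 0 in mesenchyme (3 at an unadjusted p under 0.05, 3 by DESeq2, 3 by limma-voom), and of 20 proliferation genes 0 (5 at an unadjusted p under 0.05, 0 by DESeq2, 0 by limma-voom); both counts were the same adjusted over the list alone. For proliferation the number higher in parotid mesenchyme was 4 without submandibular mesenchyme replicate 4 and 5 without parotid mesenchyme replicate 4 (range 0 to 5 with 1 library left out). Their sums were 963 ± 191 and 1000 ± 154 CPM for endothelium and 2370 ± 498 and 2280 ± 188 CPM for proliferation. Erythroid genes had 0 calls of 9 by edgeR in epithelium (2 at an unadjusted p under 0.05, 1 by DESeq2, 0 by limma-voom, 0 adjusted over the list alone) and 1 lower in mesenchyme, also adjusted over the list alone. They summed to 1750 ± 312 CPM in parotid and 3630 ± 383 CPM in submandibular mesenchyme, where the libraries of the glands did not overlap. The 5 genes of sex chromosome balance had 0 calls in either gland comparison (0 at an unadjusted p under 0.05, 0 by DESeq2, 0 by limma-voom, 0 adjusted over the list alone). Of 3 tested HOX genes 2 were lower in parotid epithelium and 1 was higher in parotid mesenchyme (2 and 2 adjusted over the list alone). Schwann cell lineage genes counted 3 higher of 11 in epithelium, and 1 higher and 1 lower in mesenchyme, also adjusted over the list alone. In mesenchyme 1 to 2 of them were higher and 0 to 3 lower with 1 library left out.

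Whether the gland difference was the same in both layers was tested by the interaction of gland and layer. The gland difference of Gata2 was larger in epithelium, with an interaction of log2 6.42 (SE 0.63), and the gene stood at 5.75 ± 2.22 and 6.03 ± 1.93 CPM in the mesenchymes. Areg went opposite ways, higher in parotid mesenchyme and lower in parotid epithelium, where it stood at 0.106 ± 0.106 against 2.11 ± 0.523 CPM. Prlr, lower in parotid mesenchyme, was at 2.02 ± 0.734 against 0.58 ± 0.257 CPM in epithelium (interaction log2 8.80, SE 0.64, adjusted p = 1.14e-07 by edgeR's quasi-likelihood test). Kcnj12, a potassium channel gene, was at 0.322 ± 0.268 against 17.3 ± 3.19 CPM in mesenchyme and 0.49 ± 0.296 against 0.0546 ± 0.0452 CPM in epithelium. Gabrp, a GABA receptor subunit gene, was at 1.59 ± 0.922 against 42.9 ± 8.35 CPM in epithelium and had 44 counts in parotid and 0 in submandibular mesenchyme.

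The interactions of Acan, Rxfp1 and Krt4 were also called, with adjusted p of 1.13e-05, 2.14e-07 and 0.000247. Their sizes rest on groups with few counts and depend on the prior count, and the call for Krt4 was lost without parotid mesenchyme replicate 1. In all, 3799 genes had an interaction, 1577 positive and 2222 negative, and 1703 genes were called in both gland comparisons. Of these, 843 were higher in parotid tissue in both layers, where independent lists of these sizes would share 423, and 378 were lower in both, where 243 would be shared. The other 482 (28.3%) went opposite ways. Across all 18191 genes, which are not independent replicates, the gland differences of the layers had a correlation of 0.179. Camera called 6 lists, none with an estimated correlation (3 had an unadjusted p under 0.05 there). Without parotid epithelium replicate 4 it called 11 lists. Lists outside the 6 that were called in several of the fits without 1 library were neurotrophic factors and axon guidance (adjusted p 0.00638 to 0.101), FGF response and receptors (0.0168 to 0.158) and the EGF, neuregulin and EDA pathways (0.0218 to 0.107). Retinoic acid genes counted 8 positive and 2 negative of 16 (9 and 3 adjusted over the list alone; adjusted p = 0.0148, and adjusted p = 0.24 with an estimated correlation; 0.00583 to 0.0414 with 1 library left out). Stratified epithelium genes had 6 negative of 12, also adjusted over the list alone. The number was 3 without parotid mesenchyme replicate 1 (range 3 to 7 with 1 library left out). Camera gave adjusted p = 0.0012 (8.04e-05 to 0.0148 with 1 library left out), and adjusted p = 0.241 with an estimated correlation. Duct and basal genes had 6 negative of 13, also adjusted over the list alone (adjusted p = 0.0109, and adjusted p = 0.672 with an estimated correlation), a call lost without parotid mesenchyme replicate 1, the library of that group with the most epithelial marker counts (0.123, within a range of 0.00142 to 0.123). Endothelial genes counted 7 positive and 1 negative of 17 (10 and 1 adjusted over the list alone), with adjusted p = 0.00421 (1e-04 to 0.0489 with 1 library left out) and adjusted p = 0.672 with an estimated correlation. The number positive was 4 without parotid epithelium replicate 4 or submandibular epithelium replicate 2 (range 4 to 10 with 1 library left out). Macrophage and leukocyte genes counted 4 positive and 0 negative of 12 (7 and 0 adjusted over the list alone), with adjusted p = 0.00421 (8.3e-05 to 0.0118 with 1 library left out) and adjusted p = 0.672 with an estimated correlation. Of the macrophage genes edgeR called 0 to 2 positive in 12 of the 16 fits that each left out 1 library, all but those without parotid epithelium replicate 2 or submandibular epithelium replicate 1, 2 or 3. Cartilage genes counted 3 positive and 0 negative of 10 (4 and 0 adjusted over the list alone), with adjusted p = 0.0109 (0.00279 to 0.0245 with 1 library left out) and adjusted p = 0.672 with an estimated correlation.

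Positions of the leading genes are those of the GENCODE M21 annotation of build GRCm38, counted from 1, and each value is that of a whole gene. Among genes higher in parotid epithelium lay Gata2 (ENSMUSG00000015053) at 88193891 to 88207032 on the plus strand of chromosome 6 and Il33 (ENSMUSG00000024810) at 29925114 to 29960718 on the plus strand of chromosome 19. Sp5 (ENSMUSG00000075304) lay at 70474923 to 70477729 on the plus strand of chromosome 2 and Tbx2 (ENSMUSG00000000093) at 85832551 to 85841948 on the plus strand of chromosome 11. Among genes lower there lay Tlx1 (ENSMUSG00000025215) at 45150680 to 45156943 on the plus strand of chromosome 19 and Krt4 (ENSMUSG00000059668) at 101918535 to 101924735 on the minus strand of chromosome 15. Foxa1 (ENSMUSG00000035451) lay at 57540628 to 57546916 on the minus strand of chromosome 12 and Rxfp1 (ENSMUSG00000034009) at 79641611 to 79737880 on the minus strand of chromosome 3. Genes higher in parotid mesenchyme included Vstm2a (ENSMUSG00000048834) at 16257724 to 16427310 on the plus strand of chromosome 11 and Cxcl14 (ENSMUSG00000021508) at 56288643 to 56296551 on the minus strand of chromosome 13. Areg (ENSMUSG00000029378) lay at 91139599 to 91148432 on the plus strand of chromosome 5. Pantr1 and Pou3f3 are neighbours transcribed away from each other with no shared exon: Pantr1 (ENSMUSG00000060424) at 42590782 to 42694842 on the minus strand of chromosome 1 and Pou3f3 (ENSMUSG00000045515) at 42695768 to 42703176 on the plus strand of chromosome 1. Genes higher in submandibular mesenchyme included Acan (ENSMUSG00000030607) at 79053483 to 79115099 on the plus strand of chromosome 7 and Nr5a2 (ENSMUSG00000026398) at 136842571 to 136960448 on the minus strand of chromosome 1. Prlr (ENSMUSG00000005268) lay at 10177238 to 10349180 on the plus strand of chromosome 15. Fgf10 (ENSMUSG00000021732) lies at 118669791 to 118792115 on the plus strand of chromosome 13, and 2.67% of its exon bases overlap a gene on the other strand.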

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

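The test of a batch shared by the layers, and those of duct cells and of stratified epithelium, had their limits set after the results were seen; the tests of mesenchyme carry-over and of other splits of the libraries were set before. In 37 of 338 groups of 4 libraries 1 library lay far from the other 3. Chance gives about 1 in 20 for normally spread values, but the check ran on CPM without a log. Some of these groups held few counts, such as Prom2 and Th in parotid mesenchyme with 1 count in all, where a single read sets a library apart. The excess over that rate can therefore not be read as outlying libraries alone.

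Values far from the other 3 were, in parotid epithelium, Il33 at 66.4 CPM in replicate 2 against 184 to 190, Plcb1 at 56.5 CPM in replicate 4 against 48.4 to 49 and Foxe1 at 1.3 CPM in replicate 4 against 0.141 to 0.254. Scel at 0.297 CPM in replicate 1 against 0 to 0.0469, Htr7 at 0 CPM in replicate 3 against 0.0424 to 0.0482 and Krt19 at 9.43 CPM in replicate 3 against 4.67 to 5.3 stood apart there. Summed CPM of erythroid cells at 495 CPM in replicate 4 against 59.4 to 119 stood apart there. In submandibular epithelium they were Wfdc18 at 2.75 CPM in replicate 4 against 0.477 to 0.647, Tbx2 at 5.68 CPM in replicate 3 against 1.15 to 1.54 and Htr7 at 0.147 CPM in replicate 4 against 0. Krt5 at 223 CPM in replicate 3 against 67 to 86, Dkk2 at 8.01 CPM in replicate 3 against 0.322 to 1.32 and summed CPM of epithelial identity at 6610 CPM in replicate 3 against 4660 to 4850 stood apart there. Summed CPM of bone at 45.6 CPM in replicate 4 against 30 to 30.3 stood apart there. Parotid mesenchyme had Prlr at 1.15 CPM in replicate 2 against 0.158 to 0.327, Prom2 at 0.0536 CPM in replicate 1 against 0 and Krt4 at 0.322 CPM in replicate 1 against 0. Gabrp at 2.09 CPM in replicate 1 against 0 to 0.274, Rspo2 at 81.1 CPM in replicate 3 against 40.3 to 44.5 and Tbx15 at 122 CPM in replicate 1 against 86.3 to 89.3 stood apart there. Th at 0.0536 CPM in replicate 1 against 0, Myh3 at 27.8 CPM in replicate 4 against 193 to 199 and summed CPM of epithelial identity at 79.4 CPM in replicate 1 against 17 to 25 stood apart there. Submandibular mesenchyme had Pantr1 at 0.0999 CPM in replicate 2 against 0, Hrh1 at 0.102 CPM in replicate 1 against 0 and Tmprss2 at 0.0499 CPM in replicate 2 against 0. Cldn6 at 1.14 CPM in replicate 3 against 0 to 0.153, Rxfp1 at 1.86 CPM in replicate 3 against 0.0999 to 0.327 and Krt4 at 0.103 CPM in replicate 3 against 0 stood apart there. Fst at 13 CPM in replicate 1 against 7.73 to 8.59, Prph at 0.568 CPM in replicate 3 against 0 to 0.0544 and Tnnc1 at 13.4 CPM in replicate 3 against 5.87 to 6.64 stood apart there. Acta2 at 51.6 CPM in replicate 3 against 35.2 to 36.8, Col9a1 at 29.5 CPM in replicate 4 against 3.6 to 7.2 and Lama1 at 90.5 CPM in replicate 4 against 64.6 to 69 stood apart there. Col4a5 at 45.2 CPM in replicate 4 against 58.3 to 60.2 and Crabp1 at 31.4 CPM in replicate 4 against 16 to 17.7 stood apart there.

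The gland difference, parotid minus submandibular, differed between the layers for 74 of the 112 named genes tested and for 3799 genes in all, by the interaction test in edgeR. The latter are 20.9% of all genes tested. The named genes were picked for large changes in a gland comparison or in the interaction, so a higher share among them was likely from the way they were picked. On the log2 scale the difference in epithelium minus that in mesenchyme was 8.89 for Kcnj12, 8.8 for Prlr, 6.81 for Gpat3, 6.42 for Gata2, 6.3 for Tmc3, 5.33 for Col4a6, 4.84 for Eda2r, 4.7 for Phex, 4.36 for Il33, 4.06 for Rdh10, 3.91 for Gdnf and 3.46 for Col4a5. It was also 3.32 for Plcb1, 3.18 for Kdr, 3.09 for Bmp7, 3.08 for Tbx2, 3.03 for Twist2, 2.99 for Lama1, 2.75 for Col9a1, 2.54 for Tgfa, 2.17 for Cyp26a1, 2.14 for C1qa, 2.12 for Bmp2 and 2.01 for C1qc. Smaller positive values were 1.89 for Axin2, 1.19 for Nkd2 and 0.743 for Pfkl. Lower in epithelium than in mesenchyme, the difference was -11 for Scel, -8.18 for Bmp3, -7.43 for Fst, -7.24 for Btc, -6.98 for Tbx1, -6.75 for Mgat4c, -6.67 for Krt5, -6.54 for Cdh8, -6.45 for Krt6a, -6.28 for Cxcl14, -6.22 for Isl1 and -5.92 for Foxa1. Next came -5.75 for Fgfr3, -5.28 for Lama3, -5.06 for Krt15, -4.89 for Sema3c, -4.68 for Wnt7b, -4.6 for Nrg1, -4.59 for Pou3f3, -4.56 for Rgs5, -4.47 for Krt19, -4.4 for Barx1, -4.13 for Id1 and -3.85 for Myh3. The value was -3.47 for Fgf13, -3.46 for Sox9, -3.28 for Sema3e, -2.69 for Fgf9, -2.63 for Cftr, -2.63 for Bmp4, -2.52 for Mylpf, -2.4 for Ntn1, -2.24 for Acta2, -2.16 for Postn, -1.65 for Apcdd1 and -1.51 for Lef1. There were values of -1.1 for Ldha and -0.631 for Eno1. For genes with 3 or fewer counts in a group the fitted value depends on the prior count, is no bound and has no place in this order. Such values were 8.72 for Acan, 2.95 for Aldh1a1, -13.1 for Areg, -11.4 for Gabrp, -8.33 for Hrh1, -11.8 for Krt4, -7.54 for Pantr1, -13 for Rxfp1 and -10.5 for Tlx1. The ERCC features, which no comparison used, held 10489 counts over the 16 libraries.

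The gland calls could come from a library batch, since the blocks of numbers in the sample names follow the glands. The blocks also follow the layers within a gland, so the layer calls and the interaction share this limit. If a batch acted alike on both layers, genes called in both gland comparisons would go the same way. Of the 1703, 28.3% went opposite ways, so such a batch is not the whole cause. It stays open as a part, since sharing in the same direction exceeded that of independent lists (843 against 423 higher, 378 against 243 lower). A gland difference common to the layers would give this too, and so would mesenchymal cells left on the epithelium, which are weighed below. A batch that acts on each layer differently cannot be told apart from the gland. In fits to the 8 libraries compared, 1 of 35 splits, the real one, reached 2738 calls in epithelium (highest other 8). In mesenchyme 1 of 35 reached 6707 (highest other 2). Every other split mixes libraries of the labelled groups and so raises the spread within a group, which by itself leaves few calls. These splits therefore cannot exclude chance, and 1 of 35 is the smallest share they can give. Among the 7 other splits of the epithelia that part all 4 numbered pairs the highest was 0. Between the layers 1 of 35 splits, again the real one, reached 10667 in parotid gland (highest other 1) and 11527 in submandibular gland (highest other 1). For the interaction it was 1 of 100 draws (3799, highest other 583). Those draws shuffle libraries over all 4 groups and so mix the layers too, with the same limit.

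Genes called higher in parotid epithelium might come from mesenchymal cells left on it. The summed mesenchymal markers allow 2.02% of parotid mesenchyme, and 96.5% of the 2033 genes, that is 1961, exceeded what this share would bring. Carry-over of that size is therefore not the whole cause for these 1961, and stays open for the other 72. With the genes left out whose mean was higher in the mesenchyme than in the epithelium of either gland, 677 genes were called higher in parotid epithelium. Macrophage markers stood at 24.2% of their level in mesenchyme in parotid epithelium and 10.5% in submandibular epithelium, with C1qc at 4.06 ± 1.07 CPM in parotid epithelium. At the larger share of 24.2% only 1174 of the 2033 genes exceeded the allowance, so carry-over of that size stays open for all the others. Whether the tissue itself holds more macrophages was not tested.

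A smaller share of duct and basal cells in parotid epithelium could lower their genes together, and oral epithelium carried into the submandibular libraries could raise stratified genes there. In the duct and basal list, with a median log2 fold change of -1.37, 4 of 13 members had an interval wholly above the median, namely Trp63, Prom1, Hey1 and Krt14. In the stratified list, with a median of -2.31, it was 5 of 12, namely Krt10, Perp, Krt17, Krt1 and Ivl. Cells other than the named type also express these genes, and a type may change its expression, so neither count decides, and a lower level per cell in parotid epithelium, named by the design as a gland difference, stays open too.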

How the results depend on the processing

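The alternatives that leave out a pair of libraries were chosen after seeing the data; the others were set before. The named genes followed here were those taken for the largest changes in these same data, not genes named only as list examples. Their stability was therefore likely from the way they were picked. Of 1079 values of these named genes under an alternative, 1078 kept their direction and side of the threshold and 0 reversed. The other 1 was no longer past it, the interaction of Krt4 without parotid mesenchyme replicate 1. All 6 counts of Krt4 in parotid mesenchyme lay in that library (0.322 CPM against 0 in the others), so without it the group had no count. Of the 10 counts of genes or lists, 142 values under an alternative stayed within 1.5 times and 24 did not. Requiring more than a 1.5-fold change by glmTreat left 930 genes in epithelium, 2346 in mesenchyme, 7113 in parotid, 7640 in submandibular gland and 1572 for the interaction. With fewer genes tested, leaving out genes higher in the other layer gave 1399 in epithelium and 2898 in mesenchyme. Without parotid epithelium replicate 4 and submandibular epithelium replicate 1 the epithelium count was 1846, with fewer libraries. Leaving out 1 library at a time gave 2452 to 4540 genes in epithelium (2452 without submandibular epithelium replicate 1), 5325 to 5970 in mesenchyme, 11200 to 11627 in parotid, 11645 to 12032 in submandibular gland and 3152 to 3922 for the interaction. DESeq2 called 4590, 6689, 11859, 12226 and 4444 genes in these 5 comparisons.

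Camera with an estimated correlation called 1 list in epithelium and 0 in mesenchyme, 0 in parotid, 0 in submandibular gland and 0 for the interaction (4, 0, 4, 6 and 3 at an unadjusted p under 0.05), while fry, which asks another question, called 12, 14, 26, 25 and 10. Leaving out 1 library gave 9 to 12 lists in epithelium, 2 to 6 in mesenchyme, 11 to 16 in parotid, 12 to 14 in submandibular gland and 6 to 11 for the interaction (11 without parotid epithelium replicate 4). In mesenchyme it was 4 without parotid replicate 1, 4 without parotid replicate 3, 6 without parotid replicate 4, 5 without submandibular replicate 2 and 4 without submandibular replicate 4. In the layer comparisons WNT response was lost in parotid gland without parotid epithelium replicate 3 (0.0507) or parotid mesenchyme replicate 2 (0.0537; range 0.0267 to 0.0537), and the BMP pathway in submandibular gland without submandibular mesenchyme replicate 4 (0.051; range 0.0131 to 0.051).

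With the replicate number as a block 3980 genes were called in epithelium (3556 of them also without it), 6343 in mesenchyme, 11803 in parotid, 12176 in submandibular gland and 3871 for the interaction, and 11, 3, 13, 13 and 8 lists. In epithelium, where the numbers were taken to pair the libraries, the block ended none of the 11 list calls, added none, and changed no call of a named gene. That fit held all 16 libraries and gave each number the same effect in all 4 groups. It is therefore no paired test of the epithelia alone, and the main calls did not use the pairing. Outside the epithelia the numbers did not meet the limit of 0.1 for pairing. The correlations were -0.054 to -0.0027 in mesenchyme, -0.15 to -0.067 in parotid and 0.048 to 0.38 in submandibular gland, and 0, 0 and 5 of 8 libraries correlated best with their own number. In the submandibular gland only the correlation of 0.048 fell under the limit, so pairing there is undecided. Genes with few counts limit the rest, since folds against a group with 0 to 3 counts are bounds or carry wide counting intervals.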

Other observations

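All values in this part were picked after the data were seen, and no test beyond those already described was added. In epithelium, of 18 genes of the EGF, neuregulin and EDA pathways 2 were higher and 5 lower in parotid tissue (2 and 7 adjusted over the list alone). The number lower was 3 without parotid epithelium replicate 2 or submandibular epithelium replicate 1 or 3. Tgfa, a gene of an EGF receptor ligand, stood at 16.1 ± 5.31 CPM (SD, n = 4) in parotid against 3.66 ± 0.908 CPM in submandibular epithelium. Of 20 genes of neurotrophic factors and axon guidance 3 were higher and 3 lower, also adjusted over the list alone, and 5 were lower without submandibular epithelium replicate 4. Genes of hypoxia and glycolysis summed to 7880 ± 770 against 5160 ± 750 CPM in the epithelia and 2940 ± 190 against 1620 ± 127 CPM in the mesenchymes, parotid first. Mitochondrially encoded genes summed to 4230 ± 487 against 7140 ± 1610 CPM and 4880 ± 781 against 5960 ± 412 CPM in the same order. HOX genes, which mark positions along the body axis, summed to 0.117 ± 0.0913 and 2.08 ± 0.697 CPM in the epithelia and 2.14 ± 0.825 and 0.297 ± 0.211 CPM in the mesenchymes.

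RNA of sex-linked genes differed between libraries with the same replicate number. In parotid epithelium replicate 1 Xist, the RNA of the inactive X chromosome, stood at 159.5 CPM and the Y-linked gene Ddx3y at 0.127 CPM, and in parotid mesenchyme replicate 1 they stood at 0.107 and 194 CPM. Erythroid genes summed to 739 CPM in submandibular epithelium replicate 1 and 495 CPM in parotid epithelium replicate 4, against group means of 236 and 184 CPM.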
